A study of Mus musculus with 17 samples.

How the data were processed

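CUT&RUN libraries of peeled mouse urothelium, about 500000 cells per condition, were made with antibodies against STAG2, LIN54 and p130 from Stag2-WT and Stag2-KO animals 1 week after TMX induction. The labels list 17 samples, of which 15 have a peak list, and the 2 pMNase control samples were not used here. Per the submitters' processing notes, bcl2fastq, Bowtie2 and MACS2 were used with genome build mm10, with versions and settings not given in the sources used here. Whether a control library entered the peak calls is also not given.

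Each deposited peak has a fold enrichment at its summit, a ratio of pileup to the background that MACS2 estimated in the same library. The deposited lists also give −log10 p and −log10 q per peak. The deposited score of a peak is the whole part of its −log10 p times a constant and was not used. All of these are the authors' values within one library, so they served to describe, rank and filter peaks and were not tested between genotypes. Depth was recovered from the fold and p of each summit, which together give a fragment count and a background coverage. In each library, 99.9869% to 99.9977% of summits gave a whole count to within 0.0002 on the log10 scale, and the background coverage was 1.28 to 2.03 fragments per base. A peak that is absent from a list was not detectable at that depth.

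Peaks on chromosomes 1 to 19, X and Y were kept. A rule fixed one threshold for all libraries: the strictest of −log10 q 2, 5, 10 and 20 at which each library keeps at least 10000 peaks, and otherwise the deposited lists. No such threshold was reached, so the deposited lists (p up to 0.05) are the main setting, and q 0.01 is given beside them. A gene end was occupied when a summit lay within 500 bp of either end of a gene. The gene table (GRCm38.p6, the assembly of mm10, 21887 protein-coding genes) gives no strand, so either end was taken in place of the 5′ end. Ends shared by neighbouring genes are not told apart.

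The library was the unit of comparison, each antibody on its own. Between genotypes, the log2 number of peaks, the percent of peaks at gene ends and the log2 odds ratio of a gene list (0.5 added to each cell) were compared by two-sided exact permutation tests. The mean Jaccard index within minus between genotypes had a one-sided exact permutation test. Regions were peaks of one antibody merged where they shared at least 1 bp. Regions and genes with a peak in every library of one genotype and none of the other were counted and set against the other splits of the same libraries, which are too few for a share under 0.05. Within a group, list genes with a peak in every library were set against all other genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 90 tests per threshold. Gene ends shared by antibodies were tested in the same way. The differences of list odds ratios were adjusted over 45 tests, the lists among genes shared by antibodies over 24 and those among one-genotype genes, set against all genes marked in every library of that genotype, over 180.

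The 15 gene lists were DREAM targets of G2/M (61 genes) and G1/S (68), DREAM and MuvB subunits (14), cohesin (15), luminal (22) and basal (13) urothelium, fibroblast (12), smooth muscle (10), immune (14) and endothelial (10) markers, ribosomal protein genes (60), immediate early genes (21), p53 targets (16), genes of other tissues (30) and olfactory receptors (1110). All their genes matched the gene table, and Rbl1 stands in both the G1/S and the subunit list. Lists, tests, the threshold rule, the rule for named genes and most alternative settings were fixed before the data were examined. Genes were named by rule: Stag2, Lin54 and Rbl2; per antibody and list, up to 3 genes with the best mean rank in WT and up to 3 marked in one genotype alone, in alphabetical order; and per antibody the 10 best ranked genes in each genotype and the 5 best ranked of each genotype alone. Other genes are named where a count of list members is given, and were chosen after their values had been seen.

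Alternatives were −log10 q of at least 2 and, added after the data had been seen, 5; the 20000 best peaks per library; windows of 250 and 1000 bp; summits extended by 250 bp or a summit as the criterion for a region; fewer libraries required; batch 3 alone; replicate numbers as a block; and each library left out. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The code was tested on simulated data, where a list of 200 genes planted among 21887 with a log2 odds ratio of 4.39 was recovered at 4.23. A test of sequence motifs at summits was not run, as no genome sequence was used here.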

Results

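STAG2 is a subunit of cohesin, the ring that holds and loops chromosomes, and DREAM is the complex that represses cell cycle genes in resting cells. To ask where both sit in the bladder lining, CUT&RUN was carried out on urothelium peeled from mice with an intact Stag2 gene (Stag2-WT, here WT) or without it (Stag2-KO, here KO), 1 week after TMX induction. In CUT&RUN, an antibody tethers a nuclease to a chromatin protein and the fragments released around it are sequenced. Antibodies against 3 proteins were used: STAG2, LIN54 (the DNA-binding subunit of the MuvB core of DREAM) and p130 (the pocket protein of DREAM, encoded by Rbl2). There were 2 WT and 2 KO libraries for STAG2, 3 WT and 2 KO for LIN54, and 3 WT and 3 KO for p130, all labelled as biological replicates. The STAG2 and LIN54 libraries were of batch 1, p130-WT replicate 1 was of batch 2 and the other 5 p130 libraries were of batch 3.

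The 15 peak lists held 286084 to 539200 peaks each, with p up to a limit of 0.05, and between 316 and 25859 of a list's peaks reached q 0.01. Most peaks of a list are thus weak, so values are given for the deposited lists and at q 0.01. The background coverage recovered from the lists, a measure of depth, was 1.28 to 2.03 fragments per base. A gene end was called occupied when a peak summit lay within 500 bp of either end of a protein-coding gene, and these windows cover 41.4 Mb. The share of peaks on the X chromosome was 4.14% ± 0.963 (SD, n = 3) in LIN54-WT and 0.615% ± 0.183 (SD, n = 2) in LIN54-KO libraries. It was 1.71% ± 1.00 (SD, n = 2) in STAG2-WT and 0.347% ± 0.126 (SD, n = 2) in STAG2-KO libraries. Among p130 libraries it was 5.98% in the WT library of batch 2, 0.440% and 0.465% in the WT libraries of batch 3 and 0.317% ± 0.0108 (SD, n = 3) in KO. With so few libraries, the exact permutation tests between genotypes cannot go below p = 0.333 for STAG2 or p = 0.1 for LIN54 and p130, so none can reach 0.05.

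**Figure D1:**
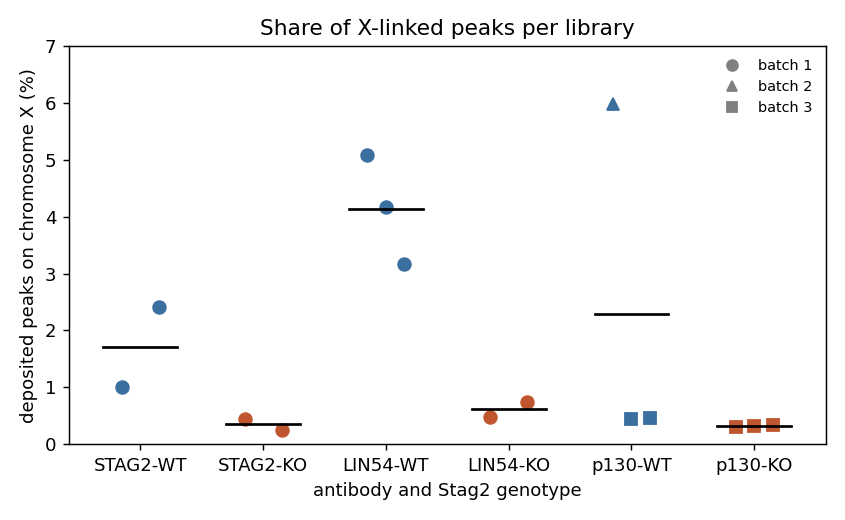
Percent of deposited peaks on the X chromosome in each library, by antibody and Stag2 genotype (blue WT, orange KO, marker shape the batch, black bar the mean). The 3 LIN54-WT libraries lie between 3.16% and 5.09% and the LIN54-KO libraries at 0.486% and 0.744%.

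The STAG2 antibody asks where cohesin with STAG2 sits in WT urothelium and what signal is left in KO. In WT, it marked immediate early genes, which growth factors and stress switch on within minutes, as well as luminal urothelial, ribosomal protein and DREAM target genes. The uroplakin gene Upk2, which builds the plaques of the bladder surface, had a mean fold enrichment over background of 10.8 ± 0.904 (SD, n = 2) in WT and 6.31 ± 2.75 (SD, n = 2) in KO. At Fos, an AP-1 transcription factor gene, these values were 12.8 ± 3.40 and 6.77 ± 0.721. At Asf1b, a histone chaperone gene, they were 12.9 ± 4.98 and 3.34 ± 1.11. The fold values are the authors' own, each scaled to its own library, and were not tested between genotypes. Upk2, Fos and Asf1b were named by their ranks in WT, a choice that favours high folds in WT. At Stag2 itself (mm10 chromosome X, 42149297 to 42277186), a STAG2 peak lay at a gene end in 1 of 2 WT libraries (q = 1.89e-08) and 1 of 2 KO libraries (q = 0.869). A peak at a gene's end does not tell whether the gene was deleted.

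Both STAG2-WT libraries had a peak at 40 of 61 G2/M genes of DREAM (mitotic genes; adjusted p = 6.90e-06) and 40 of 68 G1/S genes (replication genes; adjusted p = 0.000246, Fisher's exact test). They did so at 44 of 60 ribosomal protein genes (adjusted exact p = 1.11e-08), 17 of 21 immediate early genes (adjusted p = 9.08e-05), 15 of 22 luminal urothelial genes (adjusted p = 0.00813) and 10 of 14 subunit genes of DREAM and MuvB (adjusted p = 0.0261). Of all other genes, about 34.9% were so marked. Both KO libraries had a peak at 32 of 60 ribosomal protein genes (adjusted exact p = 1.89e-05) and 11 of 22 luminal genes (adjusted p = 0.0381), beside about 25.5% of other genes. The G2/M genes (23 of 61, adjusted exact p = 0.0946) and G1/S genes (23 of 68, adjusted p = 0.230) did not pass in KO. Without STAG2-KO replicate 1 the G2/M list passed in KO (adjusted exact p = 6.40e-05). Without WT replicate 2 the luminal genes (adjusted exact p = 0.0512) and the DREAM subunit genes (adjusted p = 0.300) no longer passed in WT. Without KO replicate 2 the luminal genes no longer passed in KO (adjusted exact p = 0.0710). At q 0.01, both WT libraries marked 14 of 21 immediate early genes (adjusted exact p = 1.16e-07) and 19 of 68 G1/S genes (adjusted p = 0.00301), and both KO libraries 4 of 21 immediate early genes (adjusted p = 0.00295). The G2/M genes (13 of 61, adjusted exact p = 0.175) and DREAM subunit genes (3 of 14, adjusted exact p = 0.777) did not pass in WT at q 0.01. Ribosomal protein genes (18 of 60, adjusted exact p = 0.00159) and luminal genes (8 of 22, adjusted exact p = 0.0162) did. In KO, ribosomal protein genes (1 of 60) and luminal genes (1 of 22) did not pass at q 0.01. Without WT replicate 2, the G2/M genes passed (adjusted exact p = 1.61e-08) and the luminal genes did not (adjusted exact p = 0.190) in WT. Without KO replicate 1, the luminal (adjusted exact p = 0.00357) and ribosomal protein genes (adjusted exact p = 0.00109) passed in KO. Olfactory receptor genes, which serve smell in the nose, were rarely marked: 53 of 1110 in WT and 59 of 1110 in KO in the deposited lists, and 0 at q 0.01 in either.

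Between genotypes, no gene list passed a test over libraries, and with so few libraries none could. The log2 odds ratio of the G2/M genes was 1.96 ± 0.01 in WT and 1.01 ± 0.95 in KO (SD, n = 2 each, exact permutation p = 0.333). That of the G1/S genes was 1.52 ± 0.50 in WT and 0.65 ± 0.10 in KO (SD, n = 2 each, exact permutation p = 0.333). For all 3 antibodies and 15 lists, 0 of 45 such differences had an exact permutation p under 0.05, adjusted or not, in the deposited lists or at q 0.01. At q 0.01, the mean number of G2/M genes with a STAG2 peak was 28.5 ± 17.7 of 61 in WT and 7.0 ± 7.07 in KO (SD, n = 2 each), and that of immediate early genes was 16.0 ± 0 and 6.5 ± 2.12 of 21. The number of all gene ends with a peak at q 0.01 was 5115 ± 1833 in WT and 1345.5 ± 1172 in KO (SD, n = 2 each).

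Genes with a STAG2 peak at q 0.01 in both WT libraries and neither KO library numbered 1354, against 7 the other way and at most 301 on one side of another split of these libraries. Among them were 11 of the 19 G1/S genes marked in both WT libraries, with the replicative helicase genes Mcm3, Mcm4, Mcm5 and Mcm7, and 7 of the 13 marked G2/M genes. Of other genes marked in WT, 49.2% were in WT alone, so neither list stood out (adjusted exact p = 1 for each). Of the 14 marked immediate early genes, 6 were in WT alone (Btg2, Hspa1a, Ier2, Ier3, Junb and Klf4, adjusted exact p = 1). These tests of one-genotype gene sets were chosen after the data had been seen. Such genes can have a deposited peak in KO: at Mcm5, both KO libraries had one, and neither reached q 0.01. Among deposited peaks, 1409 genes had a peak in WT alone and 445 in KO alone, where another split gave up to 894 on one side. Olfactory receptor genes were over-represented in both sets (32 of 53 marked in WT, adjusted exact p = 7.46e-10, and 36 of 59 marked in KO, adjusted exact p = 3.54e-23). Single WT libraries marked 19.3% and 19.9% of these genes, and single KO libraries 24.5% and 16.3%. A list marked so seldom is bound to be over-represented in such sets, so these p-values restate its rate. By rule, the genes in WT alone were led by Ell, Pi4k2a, Nlgn2, Rffl and Psmg4, and also held the cohesin genes Smc1a and Stag1. Those in KO alone were led by Ints13, Mertk, Fam83h, Wdsub1 and Grhl3, a transcription factor of barrier epithelia, and also held the basal keratin gene Krt5. As to all regions, 4300 had a peak at q 0.01 in both WT libraries and neither KO library and 11 in KO alone, where the other splits gave at most 922 in both directions together. In 313 of the 4300, no KO library had even a deposited peak. For deposited peaks the counts were 33370 and 27514, and their sum of 60884 was above the 40509 of the next split.

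Peaks at q 0.01 numbered 25859 and 13346 in WT and 1239 and 6777 in KO, a KO over WT ratio of 0.156, or −2.68 on the log2 scale (SD 0.67 in WT and 1.73 in KO, n = 2 each, exact permutation p = 0.333). The deposited lists gave a log2 ratio of −0.08 (SD 0.21 and 0.15, n = 2 each, exact permutation p = 0.667), and without WT replicate 2 or KO replicate 2 it was 0.08 or 0.03. Of peaks at q 0.01, 24.0% ± 1.78 in WT and 31.5% ± 5.50 in KO lay at gene ends (SD, n = 2 each, exact permutation p = 0.333). Of deposited peaks, 3.83% ± 0.374 and 3.24% ± 0.777 did (n = 2 each, exact permutation p = 0.667). At q 0.01, each STAG2 library overlapped some LIN54 library more than its replicate of the same genotype. The Jaccard overlap in bp of the WT libraries was 0.171, and with a LIN54-KO library up to 0.178 and 0.244. That of the KO libraries was 0.0948, and with a LIN54 library up to 0.124 and 0.213. In the deposited lists this held for the KO libraries and not for the WT libraries. The mean Jaccard overlap of STAG2 libraries at q 0.01 was 0.133 within a genotype and 0.103 between, and for deposited peaks 0.0862 and 0.0700 (n = 2 each, one-sided exact permutation p = 0.333 for both). For deposited peaks, the difference turned to −0.0134 without WT replicate 2 and fell to about 0 without WT replicate 1 (one-sided exact permutation p = 0.667 for each). A single library left out moves the q 0.01 region counts, since fewer libraries must share a region: 9010 in WT alone without WT replicate 1, 21112 without WT replicate 2 and 6990 without KO replicate 2, and 1614 in KO alone without KO replicate 1.

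**Figure D2:**
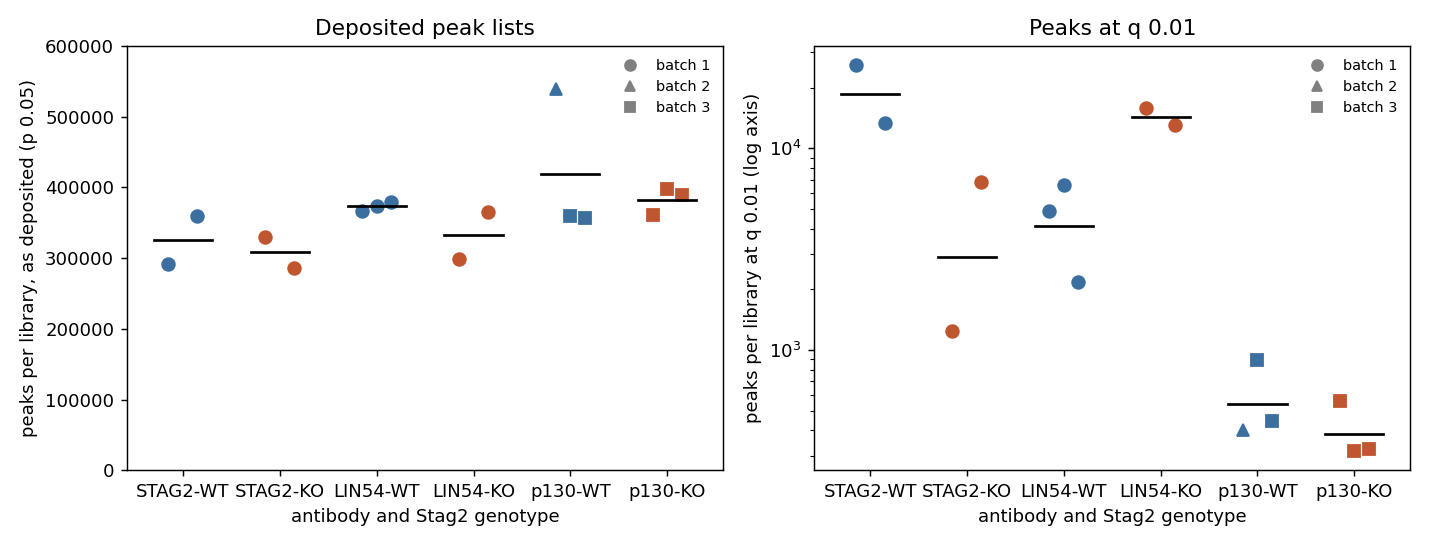
Peaks per library by antibody and Stag2 genotype (blue WT, orange KO, marker shape the batch): left, deposited lists on a linear axis with the mean as a black bar; right, peaks at q 0.01 on a log axis with the geometric mean as a black bar. At q 0.01 the LIN54-KO libraries hold 15787 and 13044 peaks and the LIN54-WT libraries 4903, 6617 and 2166.

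The LIN54 antibody asks where the MuvB core sits with and without STAG2. In both genotypes its peaks lay at mitotic, replication and ribosomal protein genes and at immediate early genes. At q 0.01 the mean log2 odds ratio was higher for immediate early genes (3.25 in WT, 3.20 in KO) than for G2/M genes (2.35 and 2.51). Signal common to open promoters was not told apart from LIN54 binding, as no control library was used here. The best ranked LIN54 end was that of Gsk3b, a kinase gene of the Wnt pathway (mm10 chromosome 16, 38089001 to 38246084). This end also ranked among the 10 best of the STAG2 antibody in KO. The end of Srgap2 ranked among the 10 best of both antibodies in both genotypes. The mean LIN54 fold at Gsk3b was 35.4 ± 5.22 (SD, n = 3) in WT and 47.5 ± 18.4 (SD, n = 2) in KO. At Cdca2, a mitotic phosphatase subunit gene whose end cannot be told from that of its neighbour Kctd9, these values were 16.4 ± 2.37 and 29.5 ± 1.53. At Top2a, the topoisomerase that untangles mitotic chromosomes, they were 8.99 ± 1.84 and 15.7 ± 5.16, at Gins2, part of the replicative helicase, 11.1 ± 1.54 and 16.2 ± 1.5, and at Egr1, an immediate early gene, 16.9 ± 6.39 and 31.4 ± 2.10. Among genes of DREAM itself, Lin52 had folds of 8.13 to 11.5 in WT and 17.7 to 18.2 in KO. At Lin54, all 5 libraries had a LIN54 peak and none reached q 0.01. At Rbl2, 2 of 3 WT and 2 of 2 KO libraries had one.

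In all 3 WT libraries, LIN54 had a peak at 37 of 61 G2/M genes (adjusted exact p = 6.36e-09), 34 of 68 G1/S genes (adjusted p = 1.28e-05), 36 of 60 ribosomal protein genes (adjusted p = 1.42e-08) and 14 of 21 immediate early genes (adjusted p = 0.000156), against 23.7% to 23.8% of other genes. In both KO libraries it had one at 46 of 61 G2/M genes (adjusted exact p = 2.38e-09), 44 of 68 G1/S genes (adjusted p = 6.90e-06), 51 of 60 ribosomal protein genes (adjusted p = 2.90e-14), 16 of 21 immediate early genes (adjusted p = 0.00102) and 10 of 14 DREAM subunit genes (adjusted p = 0.0269, or 0.218 without KO replicate 2 and 0.187 at q 0.01), against 35.4% to 35.5% of other genes. Of the genes of other tissues, 0 of 30 were marked in WT (adjusted exact p = 0.00142, or 0.152 without WT replicate 2) and 0 of 30 in KO. Of luminal urothelial genes, 9 of 22 were marked in WT and 12 of 22 in KO, which did not pass, and the list passed without WT replicate 2 (adjusted exact p = 0.00473) or without KO replicate 1 (adjusted p = 0.00779). At q 0.01, the G2/M genes passed in WT (12 of 61, adjusted exact p = 0.000158) and in KO (30 of 61, adjusted p = 1.25e-08), as did the G1/S genes (9 of 68, adjusted p = 0.0174, and 23 of 68, adjusted p = 0.00159). Ribosomal protein genes passed at q 0.01 in KO (31 of 60, adjusted exact p = 1.77e-09) and not in WT (6 of 60, adjusted p = 0.200), though they passed in WT without replicate 2 (adjusted p = 0.0448) or replicate 3 (adjusted p = 0.000385).

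More genes of these lists carried a LIN54 peak at q 0.01 in each KO library than the WT mean, and so did other genes. G2/M genes with a peak numbered 21.7 ± 4.93 of 61 in WT (SD, n = 3) and 36.5 ± 4.95 in KO (SD, n = 2), and G1/S genes 16.3 ± 4.62 and 29.5 ± 2.12 of 68. Ribosomal protein genes numbered 16.7 ± 6.66 of 60 in WT and 37.0 ± 1.41 in KO, and all gene ends 2214 ± 699 in WT and 4553 ± 247 in KO. Set against all other genes of the same library, the log2 odds ratio of the G2/M genes was 2.35 ± 0.24 in WT (n = 3) and 2.51 ± 0.58 in KO (SD, n = 2, exact permutation p = 0.7). That of the G1/S genes was 1.54 ± 0.20 and 1.56 ± 0.28 (exact permutation p = 1), and that of ribosomal protein genes 1.78 ± 0.39 and 2.61 ± 0.24 (exact permutation p = 0.2). In the deposited lists the ribosomal protein genes had 2.08 ± 0.10 in WT and 3.16 ± 0.09 in KO, the smallest p the design allows (exact permutation p = 0.1, adjusted p = 0.563).

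A LIN54 peak at q 0.01 stood at 1030 gene ends in all 3 WT libraries and at 3450 in both KO libraries, where 2 libraries rather than 3 must share it, and 1002 were in all 5. These 1002 included the DREAM targets Top2a, Cdca3, Ube2c, Cdc25a, Mcm3 and Mcm4. Genes with a peak at q 0.01 in both KO libraries and no WT library numbered 873, against 4 the other way and at most 483 on one side of another split. Of the 31 ribosomal protein genes marked in both KO libraries, 10 were in KO alone, among them Rpl10a, Rpl12, Rps3 and Rps25, beside 25.2% of other marked genes (adjusted exact p = 1). So were 4 of 30 G2/M genes (Bub1, Cenpa, Incenp and Nuf2, of the kinetochore and its checkpoint) and 5 of 23 G1/S genes (Atad2, E2f1, Msh6, Pold1 and Pole2), with an adjusted exact p of 1 for each list. One of the 4 genes with such a peak in WT alone was Ccnb2, a mitotic cyclin gene, named after its values were seen. Among deposited peaks, 446 genes were marked in KO alone and 301 in WT alone, both fewer than the 465 that another split gave on one side. The only list that passed in either set was the olfactory receptors (23 of 55 marked in KO, adjusted exact p = 4.84e-13, and 14 of 27 marked in WT, adjusted exact p = 1.54e-09). As with STAG2, this restates their low rate in single LIN54 libraries (18.6% to 27.4%). The genes in KO alone were led by Use1, Chp1, Pcbp1, Wdtc1 and D16Ertd472e and included Rrm2, a ribonucleotide reductase subunit gene. Those in WT alone were led by Srcap, Ppp1r12b, Sipa1l2, Tomt and Cdk12. Regions with a peak at q 0.01 in one genotype alone numbered 3108 in KO and 5 in WT, and the other 9 splits gave at most 1225 in both directions together. In 130 of the 3108 no WT library had a deposited peak. Deposited ones numbered 26879 in KO and 6958 in WT, and the sum of 33837 lay close to the 33545 of another split.

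LIN54 peaks at q 0.01 numbered 4903, 6617 and 2166 in WT and 15787 and 13044 in KO, a ratio of 3.48, or 1.80 on the log2 scale (SD 0.83, n = 3, and 0.19, n = 2, exact permutation p = 0.1, the smallest possible). In the deposited lists the ratio lay the other way, at −0.18 on the log2 scale (SD 0.02, n = 3, and 0.21, n = 2, exact permutation p = 0.1), all KO libraries below all WT libraries. At gene ends lay 44.3% ± 11.02 of the q 0.01 peaks in WT (SD, n = 3) and 27.6% ± 2.09 in KO (SD, n = 2, exact permutation p = 0.2). For deposited peaks the order was the other way, 3.03% ± 0.161 in WT and 3.40% ± 0.335 in KO (exact permutation p = 0.3). The mean Jaccard overlap at q 0.01 was 0.250 within and 0.169 between genotypes (n = 3 and 2, one-sided exact permutation p = 0.2). For deposited peaks it was 0.0670 and 0.0599 (one-sided exact permutation p = 0.3). On chromosomes 1 to 19 alone, the log2 ratio of q 0.01 peaks was 1.82 (n = 3 and 2, exact permutation p = 0.1). Without KO replicate 1 the q 0.01 regions of KO alone numbered 7702 and without KO replicate 2 10187, since 1 library then defines them.

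The p130 antibody asks where DREAM as a whole, or p130 with E2F, sits. Its peaks lay at replication, mitotic and histone genes in both genotypes. Top2a (mm10 chromosome 11, 98992947 to 99024199) had a mean fold of 15.7 ± 2.77 in WT and 20.2 ± 5.73 in KO, and Mcm5 (chromosome 8, 75109468 to 75128439) 18.9 ± 5.61 and 12.6 ± 3.97 (SD, n = 3 each). At the shared end of the histone genes H3c1 and H4c1 the values were 17.6 ± 3.66 and 28.9 ± 9.47. At Slbp, which binds the end of histone messenger RNA, they were 15.3 ± 7.13 and 20.5 ± 4.53, and at Mdc1, a DNA damage mediator, 15.4 ± 2.99 and 23.2 ± 9.08. The DREAM subunit gene Lin52 had a peak at q 0.01 in all 6 libraries, and Rbl1, which encodes the related pocket protein p107, in 2 of 3 WT and 3 of 3 KO libraries.

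In all 3 WT libraries, p130 had a peak at 45 of 61 G2/M genes (log2 odds ratio 4.07, adjusted exact p = 2.07e-24) and 38 of 68 G1/S genes (2.93, adjusted p = 1.23e-14), against 14.1% to 14.2% of other genes. In all 3 KO libraries it had one at 38 of 61 (4.10, adjusted exact p = 4.87e-24) and 40 of 68 (3.89, adjusted p = 5.51e-24), against 8.72% to 8.73% of other genes. At q 0.01 both genotypes had 7 of 61 G2/M genes (adjusted exact p = 3.22e-06 in WT and 1.70e-06 in KO) and 12 of 68 G1/S genes (adjusted p = 2.20e-12 and 7.47e-13). Ribosomal protein genes (19 of 60, adjusted exact p = 0.00198) and immediate early genes (9 of 21, adjusted p = 0.00473) passed in WT in the deposited lists. They did not pass there at q 0.01 (1 of 60, adjusted exact p = 0.767, and 0 of 21, adjusted exact p = 1). In KO, neither did (8 of 60, adjusted exact p = 0.393, and 4 of 21, adjusted p = 0.206), but ribosomal protein genes passed there without KO replicate 3 (adjusted p = 0.00115) and immediate early genes without KO replicate 2 (adjusted p = 0.0315). The DREAM subunit genes passed in KO at q 0.01 (2 of 14, adjusted exact p = 0.0162) and, in the deposited lists, without KO replicate 1 (adjusted p = 0.00958) or 2 (adjusted p = 0.0389). In WT they passed at q 0.01 without WT replicate 1 (adjusted exact p = 0.0365).

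**Figure D3:**
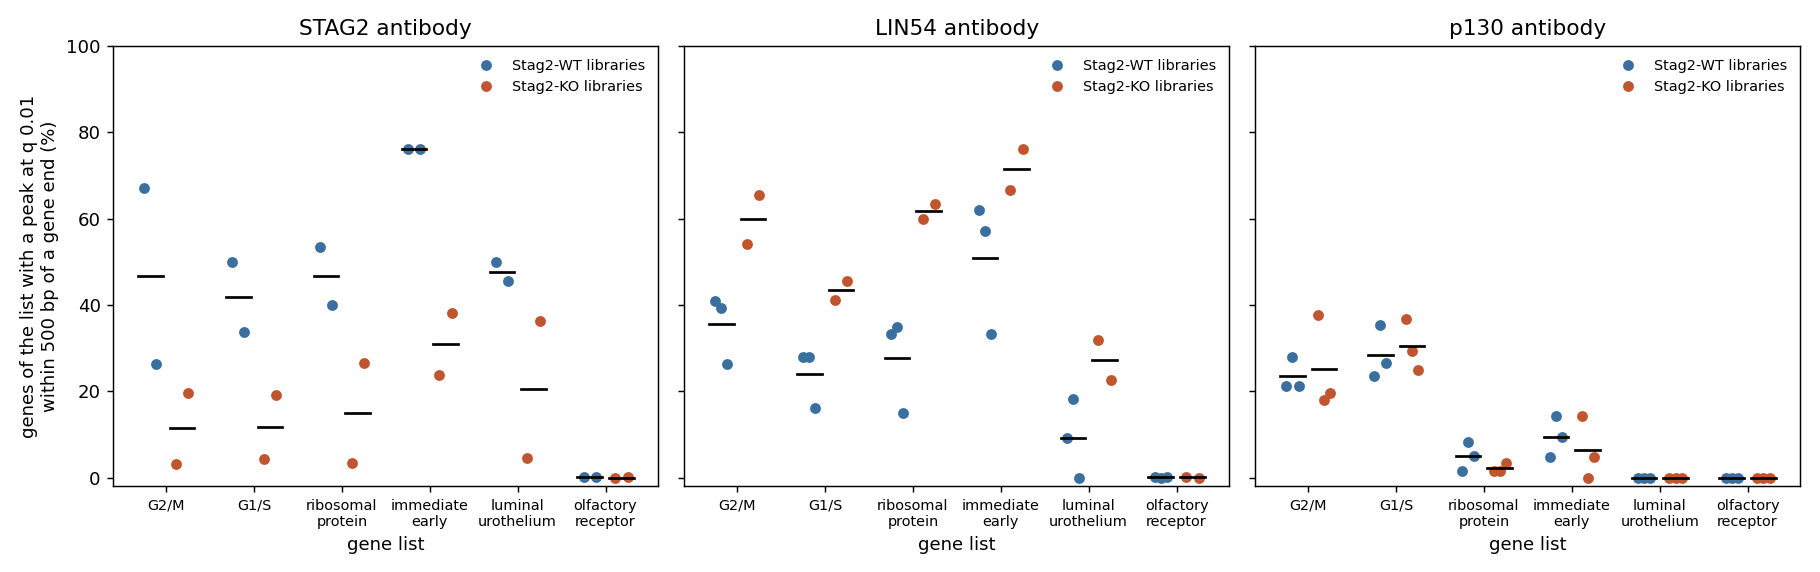
Percent of a list's genes with a peak at q 0.01 at a gene end in each library, for 6 gene lists, by antibody and Stag2 genotype (blue WT, orange KO, black bar the mean). Both LIN54-KO libraries lie above the LIN54-WT mean for G2/M genes (21.7 of 61 genes in WT and 36.5 in KO), while the p130 means are 14.3 and 15.3 genes.

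Of 166 gene ends with a p130 peak at q 0.01 in all WT libraries and 149 in all KO libraries, 112 were shared, where 1.13 would be if the sets were independent. DREAM targets made up 14.3% of them: the G2/M genes Cdc25c, Cdca2, Cdk1, Ect2, Hmgb2 and Top2a, and the G1/S genes Cdc25a, E2f1, Gins1, Gins2, Mcm3, Mcm4, Mcm5, Mcm7, Pcna and Slbp. Among deposited peaks, 529 genes had a p130 peak in WT alone and 187 in KO alone, where another split gave up to 342 on one side. No G1/S gene was among the 529, though 38 were marked in WT (17.1% of other marked genes were in WT alone, adjusted exact p = 0.0406). Single KO libraries marked 82.4%, 75.0% and 67.6% of the G1/S genes, so few could be absent from all of them. Olfactory receptor genes were over-represented in both p130 sets (12 of 27 marked in WT, adjusted exact p = 0.0215, and 13 of 33 marked in KO, adjusted exact p = 0.000148). As with STAG2, this restates their low rate in single p130 libraries (22.9% to 31.7%). By rule, the genes in WT alone were led by Pelo, Lrrc45, Hspa9 and the shared end of Slc25a27 and Cyp39a1, and held the mitotic cyclin gene Ccnb1 (fold 3.41 ± 0.499, SD, n = 3) and the stress factor gene Atf3. Those in KO alone were led by Smok2b, Prl8a2, Tmed10, Pcbp1 and Peg12, and held the exonuclease gene Exo1 and Tyms, which makes thymidylate. None of Ccnb1, Atf3, Exo1 and Tyms reached q 0.01 in any p130 library. At that threshold, 5 genes were marked in WT alone and 1 in KO alone, where another split gave 14 on one side.

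The number of G2/M genes with a p130 peak at q 0.01 was 14.3 ± 2.31 of 61 in WT and 15.3 ± 6.66 in KO, and that of G1/S genes 19.3 ± 4.16 and 20.7 ± 4.04 of 68 (SD, n = 3 each). Their log2 odds ratios were 4.12 ± 0.50 and 4.63 ± 0.22 for G2/M genes (SD, n = 3 each, exact permutation p = 0.3) and 4.49 ± 0.36 and 5.09 ± 0.29 for G1/S genes (SD, n = 3 each, exact permutation p = 0.1). In the deposited lists the KO minus WT differences were 0.08 (n = 3 each, exact permutation p = 0.9) and 0.31 (n = 3 each, exact permutation p = 0.6). Peaks at q 0.01 numbered 580.3 ± 274 in WT and 399 ± 139 in KO (SD, n = 3 each), a log2 ratio of −0.50 (exact permutation p = 0.4), and the deposited lists gave −0.10 (exact permutation p = 1), or 0.10 without WT replicate 1. At gene ends lay 61.6% ± 6.95 of the q 0.01 peaks in WT and 63.5% ± 4.96 in KO (SD, n = 3 each, exact permutation p = 0.9). Of deposited peaks, 2.58% ± 0.479 and 2.12% ± 0.116 did (n = 3 each, exact permutation p = 0.2). At q 0.01, 9 regions had a peak in WT alone and 3 in KO alone, 33 and 5 within batch 3, where 2 WT libraries remain. Leaving out one library gave 9 to 33 and 5 to 18. For deposited peaks, the counts were 8396 and 7616, or 30329 in WT alone within batch 3. The Jaccard overlap in bp of the deposited lists was 0.0421 within a genotype and 0.0298 between (n = 3 each, one-sided exact permutation p = 0.1). At q 0.01 it was 0.224 and 0.206 (one-sided exact permutation p = 0.2).

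The marker lists of other cell types passed in no group. Among the deposited peaks of STAG2-WT, 3 of 13 basal urothelial, 5 of 12 fibroblast, 0 of 10 smooth muscle, 3 of 14 immune and 2 of 10 endothelial genes were marked. In LIN54-WT these numbers were 1, 2, 1, 2 and 1, and in p130-WT 0, 2, 1, 0 and 1. The cohesin genes (9 of 15 with STAG2, 7 with LIN54 and 4 with p130 in WT) and the p53 targets (10 of 16, 5 and 4) did not pass either, though the cohesin genes passed at q 0.01 with STAG2 in WT without WT replicate 1 (adjusted exact p = 0.0307). In KO the cohesin genes numbered 3, 8 and 3 and the p53 targets 5, 7 and 0.

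The study sets STAG2 beside DREAM, so the gene ends that their antibodies share were counted. In WT and at q 0.01, LIN54 and p130 shared 122 gene ends (7.81 if independent, log2 odds ratio 5.98), STAG2 and LIN54 810 (129 if independent, 5.16), and STAG2 and p130 135 (20.9 if independent, 4.97). In KO these were 137 (23.5 if independent, 5.93), 389 (65.4, 6.47) and 39 (2.83, 4.34). In the deposited lists the log2 odds ratios were 2.54, 2.96 and 2.00 in WT and 2.37, 3.13 and 2.08 in KO, and all 6 passed Fisher's exact test. Of the 1402 gene ends with deposited peaks of all 3 antibodies in every WT library, 23 were G2/M genes (of 61, adjusted exact p = 6.34e-12) and 19 were G1/S genes (of 68, adjusted p = 8.16e-08). Of the 947 in KO, 16 were G2/M genes (adjusted exact p = 1.48e-08) and 18 G1/S genes (adjusted p = 1.59e-09). Ribosomal protein genes also passed in the WT set (10 of 60, adjusted exact p = 0.00676) and not in the KO set (4 of 60, adjusted exact p = 0.378). The 1774 gene ends with LIN54 and p130 in WT, with or without STAG2, held 32 of the 61 G2/M genes. The log2 odds ratio of G2/M genes was 3.67 there, against 3.18 with all 3 antibodies, and 4.07 against 3.02 in KO. At q 0.01, the WT set of 111 gene ends held the G2/M genes Cdca2, Ect2, Hmgb2 and Top2a (adjusted exact p = 0.000483) and the G1/S genes Asf1b, Gins2, Mcm3 and Mcm4 (adjusted p = 0.000681). The KO set of 39 held Cdca2 alone of these lists, and neither list passed there (G2/M 1 of 61, adjusted exact p = 0.138, and G1/S 0 of 68). Genes are not independent replicates, open chromatin is shared by many factors, and p130 was profiled in other batches than STAG2 and LIN54. With an equal number of peaks per library (the 20000 best), the STAG2 antibody shared gene ends with LIN54-WT in each library. The log2 odds ratios were 3.70 and 5.25 in the WT libraries and 3.79 and 4.12 in the KO libraries. Of the 1801 LIN54-WT gene ends, the WT libraries marked 1405 and 1563 and the KO libraries 834 and 1259.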

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

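The tests of antibody differences, sequencing depth, general enrichment and the p130 splits at q 0.01 were chosen only after the result was seen.

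The KO over WT ratio of the number of peaks at q 0.01 was compared between antibodies. Genotype was permuted within each antibody, so a small p speaks against no genotype effect in either antibody. It could come from 1 antibody alone and does not by itself show that the effects differ. The log2 KO over WT ratio of LIN54 minus that of STAG2 was 4.48 (permutation of genotype within each antibody p = 0.0167, the smallest of 60 permutations, adjusted over 3 comparisons 0.045). That of p130 minus LIN54 was −2.29 (permutation p = 0.03 of 200 permutations, adjusted 0.045), and that of p130 minus STAG2 was 2.18 (permutation p = 0.367). In the deposited lists, the first was −0.10 and the second 0.0741 (permutation p = 0.7 for each), so both differences belong to the stronger peaks. With one library left out, the first was 3.25 to 5.70, with a permutation p under 0.05 only without STAG2-KO replicate 1 or 2 or LIN54-KO replicate 2, and 0.0556 to 0.1 without each of the other 6. The second was −2.63 to −1.83, with a permutation p of 0.0667 to 0.113 without each LIN54 library, p130-WT replicate 2 or p130-KO replicate 2 or 3. Without a LIN54-WT library, 0.0556 is the smallest p that the permutations can give for the first difference, so those 3 settings could not pass. In the other settings that lost the call, a smallest p of 0.01 to 0.0417 was possible, so these calls depend on single libraries. Antibody and batch cannot be told apart for p130 against the others.

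LIN54 had more peaks at q 0.01 in KO than in WT. Against sequencing depth stands a difference in background coverage of 0.00218 fragments per base, below the SD of 0.0917 among WT libraries. This coverage depends on fragment length as well as on the number of reads. Deposited LIN54 peaks were on average 310 bp ± 32.1 wide in WT (SD, n = 3) and 375 bp ± 13.7 in KO (SD, n = 2). What part this difference in width has in the number of peaks was not tested. On chromosomes 1 to 19 the log2 ratio of q 0.01 peaks was 1.82, beside 1.80 on all chromosomes. A surplus of X-linked peaks in WT adds to the WT count and could not raise this ratio. The value without X therefore decides nothing about that surplus. Set against other genes, no gain at cell cycle genes in particular was seen beyond the spread over libraries. Whether the libraries were better enriched in general or also gained somewhat more at cell cycle genes stays open. The KO minus WT difference of the log2 odds ratio was 0.16 for G2/M genes (spread 0.45), higher than for 4 of the 6 lists compared (DREAM subunits, cohesin, immediate early genes and p53 targets) and lower than for 2 (luminal and ribosomal protein genes), with a median difference of 0.15. Lists with fewer than 2 marked genes on average in a genotype were left out, as was the G1/S list, with a difference of 0.02 (spread 0.24). None of the 4 was past its spread over libraries, and of the 2 only that to ribosomal protein genes was (−0.67, spread 0.36). A general gain of LIN54 binding without STAG2 also stays open, as does a difference between the animals, since the X share followed genotype among LIN54 libraries.

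STAG2 peaks shared gene ends with LIN54 peaks in KO libraries too. With the 20000 best peaks of each library, the lowest log2 odds ratio with LIN54-WT gene ends was 3.79 among KO and 3.70 among WT libraries, in a test planned ahead. By count, the KO libraries marked fewer of the 1801 LIN54-WT gene ends (834 and 1259) than the WT libraries (1405 and 1563). WT replicate 1, with the 3.70, also marked 4315 other gene ends, against 1181 and 2370 in KO. An equal number of peaks is not an equal strength, as only 1239 and 6777 KO peaks reached q 0.01. The sharing left in KO may not depend on STAG2, as open chromatin or the antibody's background would give. STAG2 protein left in KO tissue was not tested, and joint binding of STAG2 and LIN54 in WT stays open.

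In the p130 comparison, the 6 libraries can be split in 10 ways, the genotypes being 1 of them. In the deposited lists, no other split gave as many regions of one side alone as the genotypes (16012, the highest other 9047). At q 0.01, 4 of 10 gave as many, the genotype split among them (12, the highest other 17). With 10 splits, a share under 0.05 cannot be reached.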

How the results depend on the processing

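The settings with −log10 q of at least 5, those that combine q 0.01 with other libraries or chromosomes, and those for the difference between antibodies were chosen only after the result was seen. Gene ends shared by antibodies kept their direction and their call in all 112 settings run (log2 odds ratio 1.52 to 7.87). With p130, G2/M genes (3.03 to 4.83) and G1/S genes (2.60 to 5.35) stayed enriched in 30 of 30 settings each. With LIN54, G2/M genes did in 26 of 26 (1.73 to 3.70) and G1/S genes in 25 of 26 (1.22 to 2.01), the exception being WT at −log10 q of at least 5 (1.51). Over all single lists, 1116 of 1200 values kept their call, 48 lost it, 36 gained it and 0 gained the opposite call. The log2 odds ratio of a list that did not pass could still change sign. That of the endothelial genes with STAG2 in KO was negative in the deposited lists and positive at q 0.01. Tests between genotypes within an antibody could not pass 0.05 in any setting. With the replicate number as a replicate block, the log2 ratio of q 0.01 peaks was −2.68 for STAG2, 1.33 for LIN54 and −0.50 for p130, with sign-flip permutation p of 0.25 to 1 over 30 results, where 2 pairs cannot go below 0.5 and 3 pairs below 0.25. Libraries of the same number did not resemble each other (correlation −0.127 to 0.0557 at q 0.01), so pairing was not used. The motif test and the starts of all transcripts were not run, since no genome sequence and 1 span per gene were at hand. Depth limits weak peaks: at a background of 1.28 to 2.03 fragments per base, the median summit of a deposited list holds 5 to 7 fragments.

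At −log10 q of at least 2, the log2 ratio of peak numbers was −2.68 for STAG2, 1.80 for LIN54 (turned) and −0.50 for p130, and at 5 it was −3.16, 1.96 (turned) and −0.37. The differences between antibodies at q 0.01 turned to −0.10 and 0.0741 with the deposited lists. Regions in WT alone and KO alone numbered 4300 and 11 for STAG2, 5 and 3108 for LIN54 and 9 and 3 for p130 at 2. At 5 they were 1525 and 5, 0 and 1511, and 6 and 6. With the 20000 best peaks they were 2832 and 403, 45 and 2349, and 67 and 24. With no deposited peak in the other genotype they were 313 and 0, 1 and 130, and 4 and 0. LIN54 regions in WT alone were 11205 with summits extended by 250 bp. In batch 3, p130 regions were 30329 in WT alone, and 33 and 5 at q 0.01.

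The difference in percent of peaks at gene ends turned with −log10 q of at least 2 to 7.45 for STAG2, −16.7 for LIN54 and 1.92 for p130, and at 5 to 7.28, −20.9 and 4.29. With the 20000 best peaks it was −10.6, 6.29 and −2.72. The Jaccard difference was 0.0805 for LIN54 at 2, and 0.0459, 0.119 and 0.0334 for STAG2, LIN54 and p130 at 5. For p130 it was 0.00351 with the 20000 best peaks and 0.0203 where a summit had to lie in the region.

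Of lists, at −log10 q of at least 2, 1 was enriched in STAG2-KO and 2 in p130-WT. At 5 there were 2 in STAG2-WT, 1 in STAG2-KO, 1 in LIN54-WT and 2 in p130-WT. A window of 250 bp gave 3 in STAG2-WT, 1 in STAG2-KO, 2 in p130-WT and 4 in p130-KO, and one of 1000 bp gave 4 in STAG2-KO. A peak in at least 1 library gave 1 in STAG2-KO, a peak in at least 2 gave 5 in p130-KO, and the 20000 best peaks gave 2 in p130-WT. The KO minus WT log2 odds ratio of G2/M genes turned to 0.37 for STAG2 and was 0.70 for p130 at 5. That of G1/S genes was −0.14 at 2 and −0.44 with the 20000 best peaks for STAG2, −0.16 for STAG2 at q 0.01 on chromosomes 1 to 19, and 0.84 for p130 with the 20000 best peaks. It turned to −0.15 for LIN54 at 5 and to −0.18 for p130 with 1000 bp, and that of ribosomal protein genes to −0.79 for p130 at 5. The cause was not tested.

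With each library left out, fewer libraries must share a region, which raises the counts by construction. For STAG2, regions in WT alone ranged from 40398 to 268387 and in KO alone from 33552 to 250369, and at q 0.01 from 4403 to 21112 and 37 to 1614. For LIN54 the ranges were 8932 to 34117 and 31560 to 246459, and at q 0.01 14 to 55 and 3210 to 10187. For p130 they were 9904 to 40614 and 8930 to 38402, and at q 0.01 9 to 33 and 5 to 18. The Jaccard difference of STAG2 was −0.0134 to 0.0539, p130-KO had 3 to 4 enriched lists, and STAG2-KO had 1 to 3 at q 0.01.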

Other observations

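The histone gene list and the relation of X-linked to Y-linked peaks were chosen only after the result was seen.

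Replication-dependent histone genes, which supply new chromatin in S phase, were marked by all 3 antibodies. With p130, 18 of 57 had a deposited peak in all WT libraries (log2 odds ratio 1.49, adjusted exact p = 0.00126 over 12 tests) and 15 in all KO libraries (1.91, adjusted exact p = 0.000166). At q 0.01, p130 marked H2ac22, H2bc14, H2bc22, H3c1 and H4c1 in all WT libraries (3.81, adjusted exact p = 0.000144) and H3c1 and H4c1 in all KO libraries (2.73, adjusted exact p = 0.0628). LIN54 marked 30 of 57 in WT (1.83, adjusted exact p = 1.06e-05) and 42 of 57 in KO (2.32, adjusted exact p = 6.33e-08). STAG2 marked 31 of 57 in WT (1.15, adjusted exact p = 0.00395) and 25 of 57 in KO (adjusted exact p = 0.00395), and at q 0.01 19 of 57 and 1 of 57. These differences between genotypes were not tested. Histone genes lie side by side, so 1 peak can mark the ends of several.

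The share of X-linked peaks ran from 0.259% to 5.98% among the 15 libraries, and Y-linked peaks from 8 to 174. If the libraries came from animals of both sexes, libraries with more X-linked peaks would have fewer Y-linked ones: across libraries, Spearman's rho of the shares was −0.475 (permutation p = 0.0757) and Pearson's r was −0.54 (permutation p = 0.0365). Without the 2 libraries farthest in X share, r was −0.37 and rho −0.23. Within batch 1 rho was −0.63 and r −0.73 over 9 libraries, while over the 5 libraries of batch 3, too few for a test, rho was 0.30 and r −0.23, and batch 2 had 1 library. Both sexes, pooled animals or a technical loss of X-linked signal cannot be told apart, since Y-linked peaks are few and X share goes with genotype for all 3 antibodies, each WT library lying above each KO library.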
